A study of Homo sapiens with 41 samples.

How the data were processed

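Whole biopsies of transplanted kidneys were measured on 41 short-oligonucleotide Affymetrix arrays. The authors deposited 1 intensity per probe set and array on a linear scale, all above 0, and how they summarised the probes of a set and scaled the arrays is not given in the sources used here. The 75th percentiles of the arrays spanned 0.268 on the log2 scale, under the limit of 0.3 fixed for keeping this scaling, so it was kept. Direction is sirolimus minus cyclosporine throughout. The regimen was taken from the labels, which give 22 cyclosporine and 19 sirolimus arrays and no batch or date. They also number the arrays within each regimen, and what the numbers stand for is not given in the sources used here.

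Intensities under the 20th percentile of the table (21.4) were set to it and log2 was taken. A difference between dim signals is therefore understated. Probe sets were tested if they exceeded the 40th percentile of the table (36.7) in at least 19 arrays, whatever their group. The 68 control probe sets and 52 probe sets of XIST, TSIX and Y-linked genes were left out of every test, which left 13372. Genes were named from the platform annotation: 19071 probe sets carried 1 symbol, 1043 several and 2169 none, and no gene was named from a probe set with several. A gene was represented by its brightest probe set by the mean over all arrays, which gave 8306 genes.

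Each probe set was tested with limma 3.58.1 (lmFit and eBayes with a variance trend) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05, over all 41 arrays and without covariates. Each of 28 gene lists was scored per array as the mean over its members of the log2 value minus the gene's mean over the arrays. Scores were compared by a two-sided permutation test with 100000 resamples of the array labels, adjusted over the 28 lists. With the ratio as a covariate, residuals were permuted. Relations between list scores were tested within each group by Pearson's r and Spearman's rho with permutation p. A list member is said to have risen or fallen if it passed the adjusted p over all tested probe sets. A list count "adjusted over the list alone" adjusts over its members. camera with a preset correlation of 0.01 or an estimated one, and fry, were run on 1 probe set per gene.

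The genes named were chosen by a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among genes that passed, up to 4 members of each list with the smallest p, and 13 genes fixed by name, where measured. ACTA1, TNNC2, MYH2, CKM, PCK1, SLC3A1, SLC22A8, FABP4 and the other marker genes given for sirolimus replicate 15 were chosen after their values were seen, from lists fixed earlier. RNA quality was measured as the log2 ratio of the 3' to the 5' control probe set of GAPDH and of ACTB, tested by permutation, and their mean per array is called the ratio. The comparison given the ratio, the low-ratio arrays (a mean log2 ratio of at most 1), the omission of sirolimus replicate 15 and of cyclosporine replicate 20, the omission of _x_at probe sets, the split into arrays numbered 1 to 10 and 11 or more, and the arrays with a ratio of 0.8 to 1.8 were chosen after the data were seen. Whether a difference between regimens depends on this split was tested in limma with an interaction term, and for list scores by permuting the split within each regimen with 100000 resamples, both without sirolimus replicate 15. The alternatives fixed earlier were other scalings, floors, filters, variance settings, tests and thresholds, array weights, the shared numbers as a block, the omission of each array, and other tests of lists.

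The procedure was tested on simulated data with the means and spreads of the 13372 probe sets, of which 200 were changed between sirolimus and cyclosporine. Probe sets were drawn independently, without correlation between genes and without an effect of RNA quality or array number. The simulation therefore does not give error rates where these are present, as in the real arrays. Of 100 probe sets changed by 0.5 on the log2 scale 85 were called, of 100 changed by 1 all 100, and 7 unchanged ones were called. With 1 list shifted by 0.5 the list test called 1 of 28. Figures were drawn with matplotlib 3.10.9. Of the 13 genes fixed by name beforehand, 4 are not reported here.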

Results

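Gene expression was measured in biopsies of transplanted human kidneys with 1 oligonucleotide array per biopsy. The labels give the immunosuppressive regimen of each recipient: 22 arrays came from recipients on cyclosporine, a calcineurin inhibitor, and 19 from recipients on sirolimus, an inhibitor of the mTOR kinase. The title of the series, not the labels, describes transplantation that does without a calcineurin inhibitor from the start. The deposited table holds linear intensities from 8.94 to 20948 in 41 arrays. The median intensity of an array lay between 46.5 and 51.8, while the 95th percentile ran from 288 to 517, with a mean of 406 in sirolimus and 463 in cyclosporine arrays. No 2 arrays were identical. The number of arrays limits the precision of every value. The labels do not say that each array came from a separate recipient, so p-values measure the spread between these arrays. They number the arrays of each regimen from 1 upward and do not say what the order stands for.

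The comparison of sirolimus with cyclosporine asks how graft gene expression differs when the calcineurin inhibitor is replaced. UBXN4, which anchors protein degradation at the endoplasmic reticulum, fell by 1.16 ± 0.16 on the log2 scale (SE, n = 19 and 22, a 2.24-fold difference, adjusted p = 3.31e-05) and lay below the cyclosporine median in 19 of 19 sirolimus arrays. MYO6, an actin motor of endocytosis in epithelia, fell by 1.08 ± 0.17 (adjusted p = 0.000157, 19 of 19 arrays). Given the RNA quality ratio, UBXN4 differed by -1.08 ± 0.16 (adjusted p = 0.000518) and MYO6 by -1.10 ± 0.18 (0.000841). In the arrays of low ratio they differed by -1.04 ± 0.21 and -1.08 ± 0.22 (adjusted p = 0.0368 for each). Without sirolimus replicate 15 neither passed there (adjusted p = 0.055 for each). The stearoyl-CoA desaturase gene SCD5 rose by 1.47 ± 0.31 (adjusted p = 0.00172, 19 of 19 arrays), by 0.88 ± 0.20 given the RNA quality ratio described below, and differed by 0.50 ± 0.22 in the arrays of low ratio (adjusted p = 0.16). Genes of the unfolded protein response, which restores protein folding in the endoplasmic reticulum, were lower as a list, and 8 of the 16 measured members fell. This list did not pass with an estimated correlation between genes (p = 0.115, adjusted p = 0.983), given the ratio (adjusted p = 0.0658), with array weights (0.0532), with the number as a replicate block (0.0703) or in the arrays numbered 11 or more.

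The difference between regimens depended on the number of the array. Among arrays numbered 1 to 10 (10 sirolimus, 10 cyclosporine) limma called 7188 of 13372 probe sets, and among those numbered 11 or more (9 and 12) it called 0, with 683 at an unadjusted p under 0.05. Without sirolimus replicate 15, whose muscle signal is described below, it called 0 as well, with 724 at an unadjusted p under 0.05, and gene and list values for these numbers below leave that array out (8 and 12). With no difference between regimens, a share of 0.05 of the 13372 would be expected at an unadjusted p under 0.05, and 683 and 724 lie close to it. In a test of the dependence itself, 3790 probe sets passed. UBXN4 differed by -1.76 ± 0.11 in the lower and -0.60 ± 0.23 in the higher numbers, MYO6 by -1.46 ± 0.14 and -0.52 ± 0.17, and SCD5 by 2.71 ± 0.23 and 0.12 ± 0.21, each with adjusted p under 0.05 for the dependence on the number. In the higher numbers their limma p-values before adjustment were 0.0173, 0.00678 and 0.58, in this order. The 3' to 5' ratio was 0.932 or more in each sirolimus array numbered 1 to 10 and 0.67 or less in each numbered 11 to 19, so that ratio and number go together in the sirolimus arrays. Where a gene or list is said below to have risen or fallen with no number given, this holds over all 41 arrays, and no gene or list passed in the arrays numbered 11 or more. The split by number was chosen after the data were seen.

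Among the 12 largest falls besides UBXN4 and MYO6 were ALB (-1.36 ± 0.44, adjusted p = 0.0196), PRKAR1A (-1.16 ± 0.30), FLRT3 (-1.06 ± 0.21), GLUD1 (-1.03 ± 0.23), TNFRSF11B (-1.03 ± 0.19), CAPRIN1 (-0.99 ± 0.23), SNX2 (-0.96 ± 0.21), HACD3 (-0.94 ± 0.20), PROM1 (-0.94 ± 0.28) and CTSO (-0.93 ± 0.18), all as log2 difference ± SE. ALB encodes serum albumin. PRKAR1A encodes a regulatory subunit of protein kinase A, TNFRSF11B osteoprotegerin and CTSO a lysosomal cysteine protease. Of the 12 largest falls, ALB, PRKAR1A and PROM1 no longer passed given the RNA quality ratio described below, with adjusted p of 0.0735, 0.0505 and 0.0916. PRKAR1A shrank to -0.54 ± 0.17, while ALB was at -1.32 ± 0.47 and PROM1 at -0.75 ± 0.29, these 2 with a wider SE than before. Others still passed with falls more than 1.5 times smaller: GLUD1 -0.63 ± 0.18, CAPRIN1 -0.52 ± 0.12, SNX2 -0.58 ± 0.15 and HACD3 -0.58 ± 0.14. The largest rises after SCD5 were in RECK (0.98 ± 0.24), TCTN2 (0.97 ± 0.22), DNAH3 (0.95 ± 0.22), PNO1 (0.95 ± 0.21), CDC5L (0.93 ± 0.20), SPN (0.74 ± 0.18), ZNF835 (0.58 ± 0.13), SLC25A16 (0.57 ± 0.17), ZNF552 (0.54 ± 0.16), SLC11A1 (0.52 ± 0.10) and ZNF287 (0.51 ± 0.14). These 11 genes were each measured by a probe set of the _x_at type, whose probes can bind other transcripts too, and 14 of the 15 probe sets that rose by 1.5-fold or more were of this type against 13.9% of all tested. The other probe set of PNO1 and both other probe sets of CDC5L had the opposite sign. SPN (0.45 ± 0.15), SLC25A16 (0.32 ± 0.15), ZNF552 (0.31 ± 0.14) and ZNF287 (0.32 ± 0.12) no longer passed given the ratio, with adjusted p of 0.0605, 0.154, 0.154 and 0.0952. The rises that passed were smaller too: RECK 0.54 ± 0.17, TCTN2 0.61 ± 0.17, DNAH3 0.56 ± 0.16, PNO1 0.60 ± 0.17, CDC5L 0.62 ± 0.16, ZNF835 0.35 ± 0.10 and SLC11A1 0.37 ± 0.09. In the low-ratio arrays RECK differed by 0.28. RECK differed by 0.07 ± 0.17, TCTN2 by 0.09 ± 0.10, GLUD1 by 0.03 ± 0.23, SNX2 by 0.07 ± 0.22 and ALB by -0.77 ± 0.68 in the arrays numbered 11 or more.

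Of 28 gene lists fixed before the data were examined, 1 passed. The score of the unfolded protein response list was -0.12 ± 0.22 in sirolimus and 0.10 ± 0.13 in cyclosporine arrays (SD, n = 19 and 22), a difference of -0.22 ± 0.06 (SE, permutation p = 0.00021, adjusted over 28 lists p = 0.00588), and 16 of 19 sirolimus arrays lay below the cyclosporine median. Its chaperone genes HSP90B1 and HSPA5 fell by 0.70 and 0.62, its co-chaperone gene DNAJB9 by 0.60, and XBP1, a transcription factor of this response, by 0.44. Adjusted over the list alone, 8 members fell and 1 rose. Quantile normalization gave -0.12 (adjusted p = 0.0274), array weights -0.14 (0.0532) and the replicate block -0.22 (0.0703). Given the 3' to 5' ratio the list difference was -0.14 ± 0.05 (p = 0.00235, adjusted p = 0.0658), and 2 members, HSP90B1 and XBP1, fell. HSPA5 shrank to -0.29 ± 0.13 and DNAJB9 to -0.42 ± 0.15, neither passing. In the arrays of low ratio without sirolimus replicate 15 the list difference was -0.08 ± 0.06 (SE, n = 9 and 19). In the arrays numbered 1 to 10 it was -0.42 ± 0.07 (adjusted p = 0.00084) and in those numbered 11 or more 0.02 ± 0.04 (adjusted p = 0.979), a change that passed its own test (adjusted over 28 lists p = 0.00196). HSPA5 differed by -1.35 ± 0.20 and 0.24 ± 0.14 in these. Of the tests that work on genes, fry gave adjusted p = 0.0166, camera with a preset correlation adjusted p = 0.0603, and camera with an estimated correlation p = 0.115 (adjusted p = 0.983).

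Within the arrays numbered 1 to 10, 10 of the 28 lists passed, all lower with sirolimus. Besides the unfolded protein response these were podocyte (-0.32 ± 0.07), proximal tubule (-0.57 ± 0.15), extracellular matrix (-0.37 ± 0.10), metallothionein and oxidative stress (-0.36 ± 0.10), tubular injury (-0.37 ± 0.11), antigen presentation (-0.63 ± 0.21), fatty acid oxidation (-0.33 ± 0.11), macrophage and dendritic cell (-0.48 ± 0.17) and loop of Henle (-0.58 ± 0.21) lists. RNA quality differed in these same arrays, with a mean ratio of 1.81 in sirolimus and 0.64 in cyclosporine arrays numbered 1 to 10. Given the ratio, limma called 420 probe sets among them in place of 7188. In the arrays numbered 11 or more 0 of 28 passed in the permutation test, and 0 had an unadjusted p under 0.05. The change with the number passed for the unfolded protein response, podocyte (adjusted p = 0.0028), proximal tubule (0.049) and antigen presentation lists (0.049), and for no other of the 28.

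**Figure D1:**
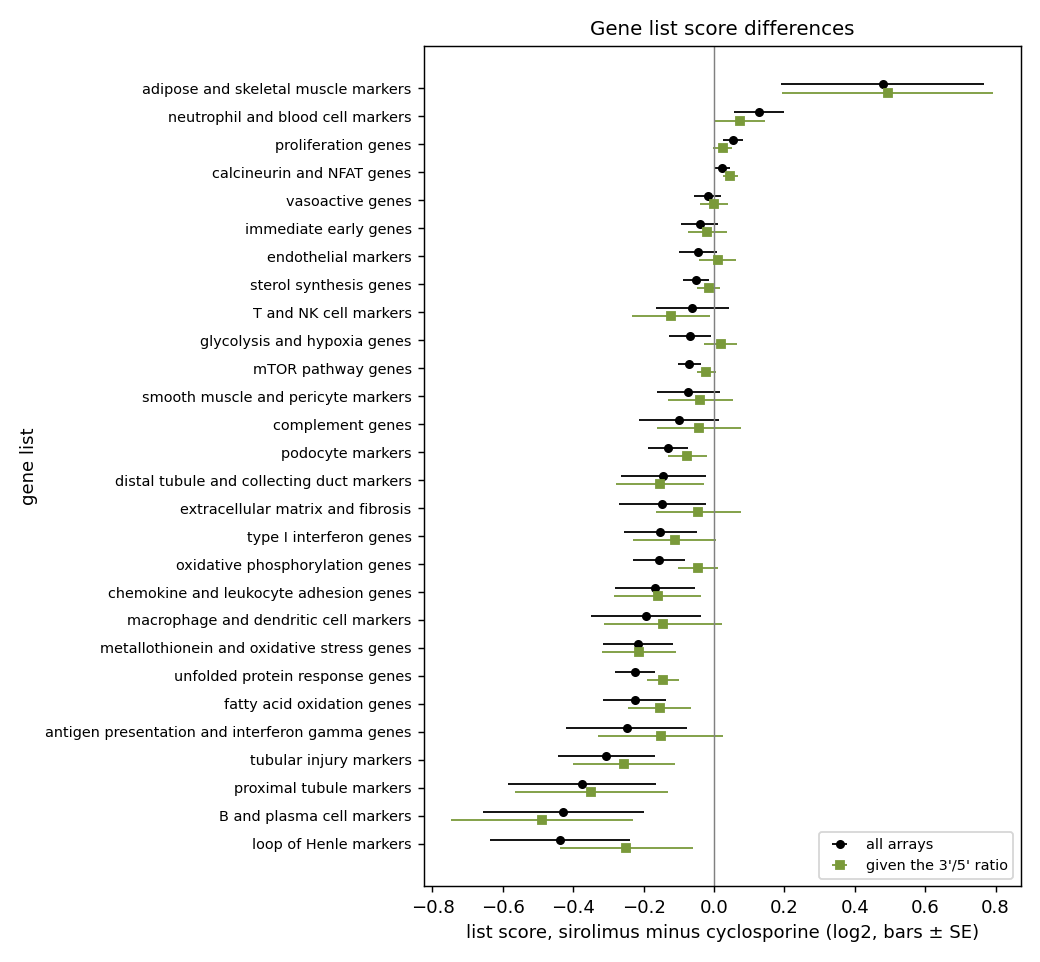
Difference of the 28 list scores, sirolimus minus cyclosporine on the log2 scale with bars of 1 SE, over all 41 arrays (black circles) and given the 3' to 5' ratio (green squares). The unfolded protein response list differed by -0.22 and, given the ratio, by -0.14.

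**Figure D2:**
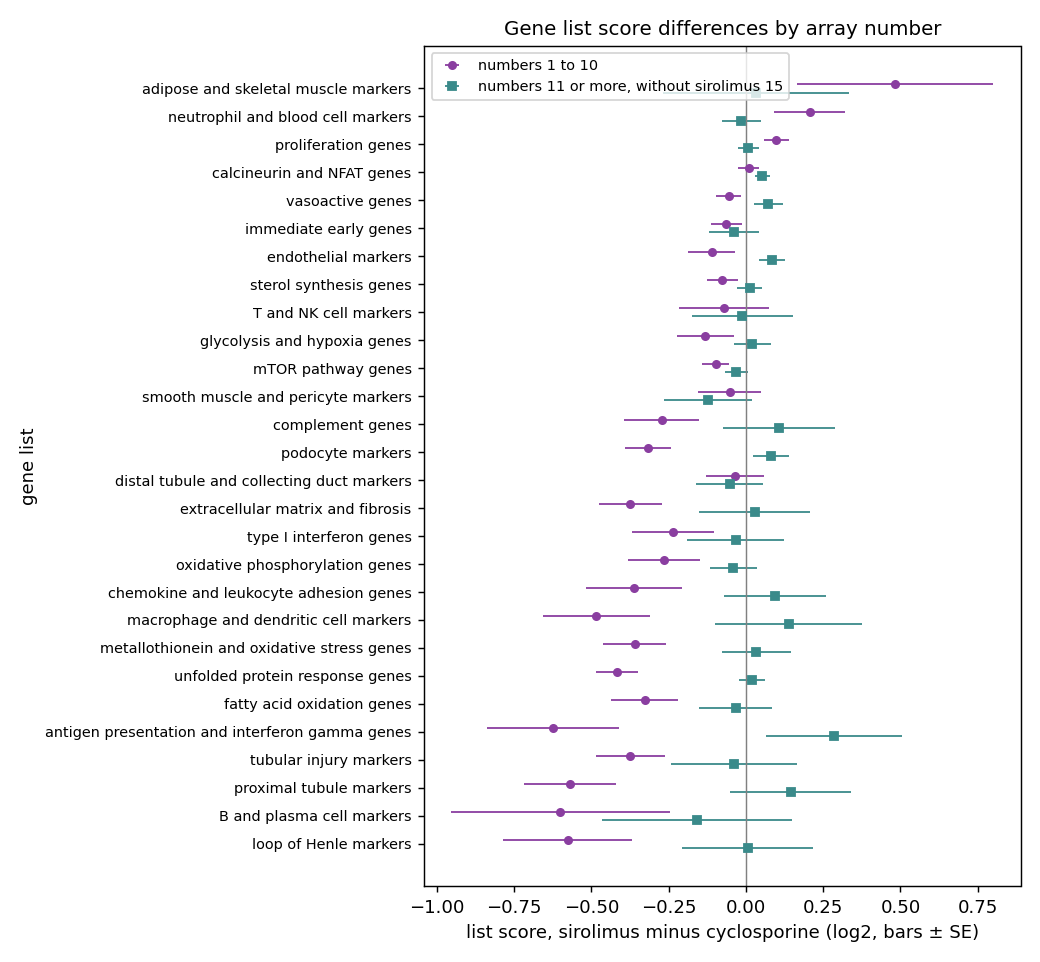
Difference of the 28 list scores, sirolimus minus cyclosporine on the log2 scale with bars of 1 SE, in the arrays numbered 1 to 10 (purple circles) and 11 or more without sirolimus replicate 15 (teal squares). The unfolded protein response list differed by -0.42 and 0.02.

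Among tubule segments, the endocytic receptor genes LRP2 and CUBN fell by 0.76 ± 0.22 and 0.81 ± 0.27, the creatine synthesis gene GATM by 0.77 ± 0.25 and the sulfate transporter gene SLC13A1 by 0.64 ± 0.16 (5 of 20 proximal tubule markers also adjusted over the list alone). The proximal tubule score differed by -0.38 ± 0.21 (p = 0.0553, adjusted p = 0.156) and, without sirolimus replicate 15, by -0.21 (p = 0.128). Given the ratio 1 of these markers fell, SLC13A1. Adjusting for the ratio took LRP2 from -0.76 ± 0.22 to -0.69 ± 0.23, CUBN from -0.81 ± 0.27 to -0.56 ± 0.27 and GATM from -0.77 ± 0.25 to -0.53 ± 0.25, with LRP2 at an adjusted p of 0.0595. The score differed by 0.15 ± 0.20 in the arrays numbered 11 or more, with LRP2 at 0.03 ± 0.21 and CUBN at 0.28 ± 0.25, against -1.23 ± 0.19 and -1.59 ± 0.31 in those numbered 1 to 10. In the thick ascending limb of the loop of Henle, the potassium channel gene KCNJ1 and the claudin gene CLDN16 fell by 0.87 and 0.57, 2 of 6 markers both over all probe sets and adjusted over the list alone, while the list score differed by -0.44 ± 0.20 (adjusted p = 0.126). None of the 16 distal tubule and collecting duct markers passed (list score -0.14 ± 0.12, adjusted p = 0.325), among them the fixed genes CALB1 (-0.46 ± 0.31, adjusted p = 0.233) and SLC12A3 (-0.28 ± 0.20, adjusted p = 0.248). Without sirolimus replicate 15 the list score differed by -0.04 ± 0.07 (adjusted p = 0.591). Of the 19 tubular injury markers 3 fell, PROM1, VCAM1 (by 0.63) and CLU (by 0.60), 2 of them adjusted over the list alone. CLU did not pass without sirolimus replicate 15 (adjusted p = 0.0706). The list score was -0.31 ± 0.14 (adjusted p = 0.126). Of 10 podocyte markers TJP1, CLIC5 and PODXL fell by 0.40, 0.45 and 0.38 (list score -0.13 ± 0.06, adjusted p = 0.126, 3 adjusted over the list alone), PODXL not without sirolimus replicate 15 (adjusted p = 0.0742). With quantile normalization the podocyte score differed by -0.04 (adjusted p = 0.639). None of the loop of Henle, injury or podocyte markers passed given the ratio. The ratio as a covariate took KCNJ1 from -0.87 ± 0.29 to -0.45 ± 0.25, CLDN16 from -0.57 ± 0.16 to -0.40 ± 0.16, VCAM1 from -0.63 ± 0.21 to -0.68 ± 0.22 and CLU from -0.60 ± 0.24 to -0.36 ± 0.23. Among podocyte genes it took TJP1 from -0.40 ± 0.13 to -0.29 ± 0.13, CLIC5 from -0.45 ± 0.17 to -0.39 ± 0.18 and PODXL from -0.38 ± 0.15 to -0.27 ± 0.15. VCAM1 differed by as much, with a wider SE, but did not pass (adjusted p = 0.0525). When each of the 41 arrays was left out in turn, the calls ended in this many omissions: CLU 26, PODXL 21 and CLIC5 19. The loop of Henle, injury and podocyte scores differed by 0.01 ± 0.21, -0.04 ± 0.20 and 0.08 ± 0.06, in this order, in the arrays numbered 11 or more.

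The mitochondrial lists did not pass over all arrays. Fatty acid oxidation genes differed by -0.23 ± 0.09 (p = 0.0149, adjusted p = 0.126), by -0.10 with quantile normalization and by -0.03 ± 0.12 in the arrays numbered 11 or more. Of 20 members 7 fell, 9 adjusted over the list alone and 0 given the ratio (list difference -0.15 ± 0.09). The acyl-CoA dehydrogenase gene ACADL fell by 0.42, the dienoyl-CoA reductase gene DECR1 by 0.41, the carnitine palmitoyltransferase gene CPT1A by 0.33 and the electron transfer flavoprotein gene ETFA by 0.46. The ratio as a covariate took ACADL from -0.42 ± 0.11 to -0.28 ± 0.10, DECR1 from -0.41 ± 0.12 to -0.28 ± 0.11, CPT1A from -0.33 ± 0.10 to -0.28 ± 0.10 and ETFA from -0.46 ± 0.14 to -0.26 ± 0.12. Oxidative phosphorylation genes differed by -0.16 ± 0.07 (adjusted p = 0.126), by 0.01 with quantile normalization (adjusted p = 0.878), which turns the direction, and by -0.04 ± 0.08 in the arrays numbered 11 or more. Of 26 members 6 fell, 6 adjusted over the list alone, led by the complex I genes NDUFS1 (-0.61) and NDUFB5 (-0.49). NDUFS1 alone of them fell given the ratio, by 0.40 ± 0.13, against 0.29 ± 0.10 for NDUFB5 (adjusted p = 0.0608). In the metallothionein and oxidative stress list (-0.22 ± 0.10, adjusted p = 0.126), 5 of 16 fell, among them the catalase gene CAT (-0.51), the glutathione synthesis gene GCLC (-0.51) and SOD1 (-0.31), 5 adjusted over the list alone and 0 given the ratio. The list difference given the ratio was nearly as before, -0.21 ± 0.11, with CAT from -0.51 ± 0.16 to -0.34 ± 0.15, GCLC from -0.51 ± 0.14 to -0.37 ± 0.14 and SOD1 from -0.31 ± 0.11 to -0.17 ± 0.10. The SOD1 call ended in 2 of the 41 single omissions. Of 21 glycolysis and hypoxia genes SLC2A3 and HK2 rose by 0.17 and 0.14 (calls that ended in 8 and 9 single omissions) and BNIP3 fell by 0.50, none adjusted over the list alone (list score -0.07 ± 0.06, adjusted p = 0.325). SLC2A3 and BNIP3 shrank to 0.09 ± 0.06 and -0.18 ± 0.11 given the ratio and did not pass. HK2 passed given the ratio but not without sirolimus replicate 15 (adjusted p = 0.0604). VEGFA, the vascular growth factor gene, differed by -0.22 ± 0.10 (adjusted p = 0.0771).

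Lists that follow the targets of both drugs showed small differences, and no mTOR, calcineurin or NFAT gene passed given the ratio. DDIT4 differed by -0.31 ± 0.22, EIF4E by -0.01 ± 0.18, FKBP1A by 0.05 ± 0.14, RCAN1 by 0.04 ± 0.13 and NFATC1 by 0.08 ± 0.08 in the arrays numbered 11 or more. The ratio as a covariate took DDIT4 from -0.55 ± 0.17 to -0.45 ± 0.18, EIF4E from -0.39 ± 0.13 to -0.20 ± 0.11, FKBP1A from -0.27 ± 0.10 to -0.11 ± 0.08, TFEB from 0.19 ± 0.07 to 0.10 ± 0.06, RCAN1 from -0.36 ± 0.13 to -0.26 ± 0.14 and NFATC1 from 0.27 ± 0.08 to 0.20 ± 0.08. Single omissions that ended a call numbered FKBP1A 20, RCAN1 10, TFEB 4 and MSMO1 4. Of 17 mTOR pathway genes, DDIT4, which restrains mTOR, fell by 0.55 ± 0.17, EIF4E by 0.39 ± 0.13 and FKBP1A, whose product binds sirolimus, by 0.27 ± 0.10, while 2 rose, among them the lysosomal transcription factor gene TFEB by 0.19 ± 0.07 (list score -0.07 ± 0.03, adjusted p = 0.126, 3 falling and 2 rising adjusted over the list alone). Of 14 calcineurin and NFAT genes, RCAN1, a calcineurin regulator that NFAT induces, fell by 0.36 ± 0.13 (adjusted p = 0.0385, and 0.057 without sirolimus replicate 15) and NFATC1 rose by 0.27 ± 0.08. This list score was 0.02 ± 0.02 higher (adjusted p = 0.379), and 0.08 higher with quantile normalization (adjusted p = 0.0106). In it 1 member rose adjusted over the list alone. PPIA, which encodes the cyclosporine-binding cyclophilin A, differed by -0.09 ± 0.10 (adjusted p = 0.495). Of 12 sterol synthesis genes, SREBF2, the regulator of this pathway, and MVD rose by 0.23 and 0.27, with 3 rising in all, while SC5D and MSMO1 fell by 0.41 and 0.44 (list score -0.05 ± 0.04, adjusted p = 0.266, 3 rising and 3 falling adjusted over the list alone). SREBF2 and SC5D passed given the ratio as well, while the covariate took MVD from 0.27 ± 0.09 to 0.28 ± 0.10 and MSMO1 from -0.44 ± 0.16 to -0.27 ± 0.15.

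No immune list passed over all 41 arrays, while the macrophage and antigen presentation lists passed in those numbered 1 to 10, as given above. The T and NK cell score differed by -0.06 ± 0.10 (adjusted p = 0.583), with CD5 rising by 0.20 as the only call among 17 genes, and the B and plasma cell score by -0.43 ± 0.23 (adjusted p = 0.193), where BLK rose by 0.13 and the immunoglobulin genes IGHM (-1.28 ± 0.52, adjusted p = 0.0516) and IGKC (-1.03 ± 0.45, adjusted p = 0.0694) did not pass. IGHM and IGKC passed in the arrays numbered 1 to 10 (-1.81 ± 0.73 and -1.64 ± 0.56, limma adjusted p = 0.0406 and 0.018). In those numbered 11 or more they differed by -0.67 ± 0.70 and -0.23 ± 0.66. The macrophage and dendritic cell score differed by -0.19 ± 0.16 (adjusted p = 0.325; MRC1 fell by 0.51), the neutrophil and blood cell score by 0.13 ± 0.07 (adjusted p = 0.193; 0 of 5 passed), the type I interferon score by -0.15 ± 0.10 (adjusted p = 0.313; 0 of 13 passed) and the antigen presentation and interferon gamma score by -0.25 ± 0.17 (adjusted p = 0.266). In the last of these B2M, the light chain of class I molecules, fell by 0.55 and CIITA rose by 0.18. The B2M difference was 0.07 in the low-ratio arrays without sirolimus replicate 15, and -1.13 ± 0.24 and 0.18 ± 0.15 in the arrays numbered 1 to 10 and 11 or more, where the list score differed by -0.63 ± 0.21 and 0.28 ± 0.22. The complement score differed by -0.10 ± 0.11 (adjusted p = 0.45), with CD59 falling by 0.61 and C4BPA and CFB rising by 0.20 and 0.31, the other probe set of CFB having the opposite sign. CFB differed by 0.30 ± 0.18 in the arrays numbered 1 to 10 (adjusted p = 0.146) and by 0.36 ± 0.13 in those numbered 11 or more. The chemokine and adhesion score differed by -0.17 ± 0.11 (adjusted p = 0.266), with VCAM1 falling and ICAM1 rising by 0.18. Adjusted over the list alone, the complement list kept 2 rises and 1 fall, the chemokine list 1 rise and 1 fall, and the other immune lists none. No member of these 8 lists passed given the ratio, which took CD5 from 0.20 ± 0.07 to 0.10 ± 0.06, BLK from 0.13 ± 0.05 to 0.11 ± 0.05, MRC1 from -0.51 ± 0.20 to -0.36 ± 0.21, B2M from -0.55 ± 0.18 to -0.28 ± 0.15 and CIITA from 0.18 ± 0.07 to 0.07 ± 0.05. In the complement and chemokine lists it took CD59 from -0.61 ± 0.18 to -0.28 ± 0.12, C4BPA from 0.20 ± 0.06 to 0.12 ± 0.06, CFB from 0.31 ± 0.11 to 0.35 ± 0.11 and ICAM1 from 0.18 ± 0.05 to 0.15 ± 0.05. CFB and VCAM1 were no smaller but had a wider SE, with adjusted p of 0.0544 and 0.0525. Leaving out 1 array ended the call in this many of 41 cases: MRC1 22, CIITA 14 and BLK 9.

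Of 31 extracellular matrix and fibrosis genes 6 fell and 1 rose (list score -0.15 ± 0.12, adjusted p = 0.325). The intermediate filament gene VIM fell by 0.75 ± 0.21, the matrix metalloproteinase gene MMP7 by 0.93 ± 0.31 and the growth factor gene CCN2 by 0.45 ± 0.16, and COL1A1 rose by 0.22 ± 0.08. Adjusted over the list alone 1 fell, and none passed given the ratio. There the differences moved, VIM from -0.75 ± 0.21 to -0.39 ± 0.16, MMP7 from -0.93 ± 0.31 to -0.82 ± 0.33, CCN2 from -0.45 ± 0.16 to -0.25 ± 0.14 and COL1A1 from 0.22 ± 0.08 to 0.18 ± 0.08. The COL1A1 call ended in 4 and the CCN2 call in 3 of the 41 single omissions. Among the arrays numbered 11 or more VIM differed by -0.05 ± 0.20, MMP7 by -0.22 ± 0.48 and CCN2 by 0.14 ± 0.18. The fixed genes TGFB1 (-0.01 ± 0.11, adjusted p = 0.927) and EDN1 (0.03 ± 0.06, adjusted p = 0.659) did not pass. In the endothelial list (-0.05 ± 0.06, adjusted p = 0.45) EMCN and KDR fell by 0.79 and 0.21 and ROBO4 rose by 0.26, the last also given the ratio. EMCN differed by -0.49 ± 0.16 and KDR by -0.16 ± 0.07 there, neither passing. ROBO4 differed by 0.31 ± 0.10 in the arrays numbered 1 to 10 and by 0.27 ± 0.07 in those numbered 11 or more (unadjusted p = 0.00055, adjusted p = 0.901). In the smooth muscle and pericyte list (-0.07 ± 0.09, adjusted p = 0.45) CALD1, ACTA2 and RGS5 fell by 0.49, 0.49 and 0.42 and SMTN rose by 0.20 (adjusted p = 0.0517 without sirolimus replicate 15). Adjusted over the list alone, the endothelial list had 2 rises and 2 falls and the smooth muscle list 2 rises and 3 falls. Among vasoactive genes (-0.02 ± 0.04, adjusted p = 0.647) EDNRB fell by 0.31 (adjusted p = 0.0514 without sirolimus replicate 15) and NOS1 and NPR1 rose by 0.14 and 0.20, 0 of them adjusted over the list alone. Of 12 proliferation genes (0.05 ± 0.03, adjusted p = 0.156) BUB1, PLK1 and MKI67 rose by 0.22, 0.21 and 0.22 and PCNA fell by 0.28, with 4 rises and 2 falls adjusted over the list alone. Of 13 immediate early genes (-0.04 ± 0.05, adjusted p = 0.465) IER3 fell by 0.45 and NR4A1 rose by 0.21, both also adjusted over the list alone. IER3 differed by -0.39 ± 0.18 in the arrays numbered 1 to 10 (adjusted p = 0.0758) and by -0.45 ± 0.18 in those numbered 11 or more. No smooth muscle, vasoactive, proliferation or immediate early gene passed given the ratio. SMTN and NPR1 were no smaller there but had a wider SE, and IER3 had an adjusted p of 0.0525. Differences moved in SMTN from 0.20 ± 0.07 to 0.22 ± 0.08, NPR1 from 0.20 ± 0.08 to 0.22 ± 0.08, NOS1 from 0.14 ± 0.05 to 0.12 ± 0.05, IER3 from -0.45 ± 0.13 to -0.43 ± 0.14 and EDNRB from -0.31 ± 0.12 to -0.22 ± 0.12. Others were CALD1 from -0.49 ± 0.15 to -0.34 ± 0.14, ACTA2 from -0.49 ± 0.17 to -0.36 ± 0.17 and RGS5 from -0.42 ± 0.16 to -0.36 ± 0.17. Cell cycle and early genes moved as well, BUB1 from 0.22 ± 0.06 to 0.14 ± 0.06, PLK1 from 0.21 ± 0.08 to 0.08 ± 0.06, MKI67 from 0.22 ± 0.09 to 0.09 ± 0.07, PCNA from -0.28 ± 0.09 to -0.17 ± 0.09 and NR4A1 from 0.21 ± 0.07 to 0.12 ± 0.06. Of 41 single omissions, those that ended the call numbered MKI67 24, NPR1 17, NOS1 15, EDNRB 14, SMTN 11, PLK1 10 and RGS5 9. BUB1 differed by 0.09 ± 0.07, PLK1 by -0.09 ± 0.10, MKI67 by -0.03 ± 0.09 and PCNA by 0.03 ± 0.12 in the arrays numbered 11 or more. At least 1 other probe set of CALD1, CLIC5 and TFEB had the opposite sign.

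Signal of skeletal muscle genes was highest in 2 arrays and present in others. In sirolimus replicate 15 the skeletal actin gene ACTA1 had an intensity of 11615.3 against a median of 40.4 in the other arrays, and the troponin gene TNNC2 14572.5 against 62. In cyclosporine replicate 20 they reached 7521 and 6323, and in the rest at most 2812 and 2390. PCK1, a proximal tubule enzyme of gluconeogenesis, had an intensity of 21.3 in sirolimus replicate 15 and at least 318.1 in each of the others. The adipose and skeletal muscle list differed by 0.48 ± 0.29 (adjusted p = 0.197) and by 0.30 without sirolimus replicate 15 (adjusted p = 0.318), and of its 7 measured genes PLIN1, which coats fat droplets, rose by 0.27 (a call that ended in 12 of 41 single omissions), 0 adjusted over the list alone. Given the ratio LPL, the lipoprotein lipase gene, passed instead (adjusted p = 0.0213), and PLIN1 differed by 0.22 ± 0.11 without passing.

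**Figure D3:**
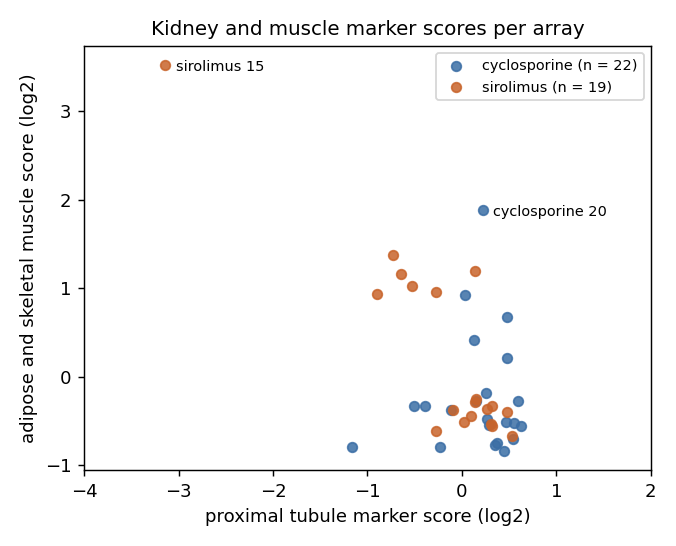
Adipose and skeletal muscle score against proximal tubule score, both on the log2 scale relative to the mean of all arrays, with 1 point per array. Sirolimus replicate 15 had the highest muscle score, 3.52, and cyclosporine replicate 20 followed with 1.88; the highest of the rest was 1.38.

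RNA quality differed between the groups. The log2 ratio of 3' to 5' signal of the GAPDH and ACTB control transcripts, which grows as RNA is degraded, averaged 1.13 ± 0.92 in sirolimus and 0.63 ± 0.41 in cyclosporine arrays (SD, n = 19 and 22, permutation p = 0.0273, adjusted over 5 measures p = 0.0455). It was above 1 in 9 of 19 sirolimus and 3 of 22 cyclosporine arrays (Fisher's exact test, p = 0.0367). Among arrays numbered 1 to 10 it averaged 1.81 ± 0.77 in sirolimus and 0.64 ± 0.24 in cyclosporine arrays (SD, n = 10 and 10, permutation p = 2e-05), and among those numbered 11 or more 0.38 ± 0.19 and 0.63 ± 0.53 (n = 9 and 12, permutation p = 0.23), where the direction turned. These 2 p-values are not adjusted. For ACTB alone the means were 0.98 ± 1.07 and 0.38 ± 0.35 (adjusted p = 0.0422) and for GAPDH 1.28 ± 0.78 and 0.89 ± 0.56 (adjusted p = 0.0835). The number of probe sets with an intensity above 500 was 884 ± 134 in sirolimus and 1019 ± 88.7 in cyclosporine arrays (permutation p on the log2 scale = 0.00026, adjusted p = 0.0013). The first principal component of the arrays held 34.2% of the variance and followed the ratio, with r = 0.805 (permutation p = 8e-05, adjusted over both groups p = 0.00016) and rho = 0.711 (p = 0.00096, adjusted p = 0.00192) within sirolimus arrays, and r = 0.706 without the 2 arrays farthest from the median ratio. Within cyclosporine arrays r was 0.744 (p = 0.00019, adjusted p = 0.00019) and rho 0.45 (p = 0.0371, adjusted p = 0.0371), and r = 0.369 without the 2 farthest, on which the relation there rests.

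**Figure D4:**
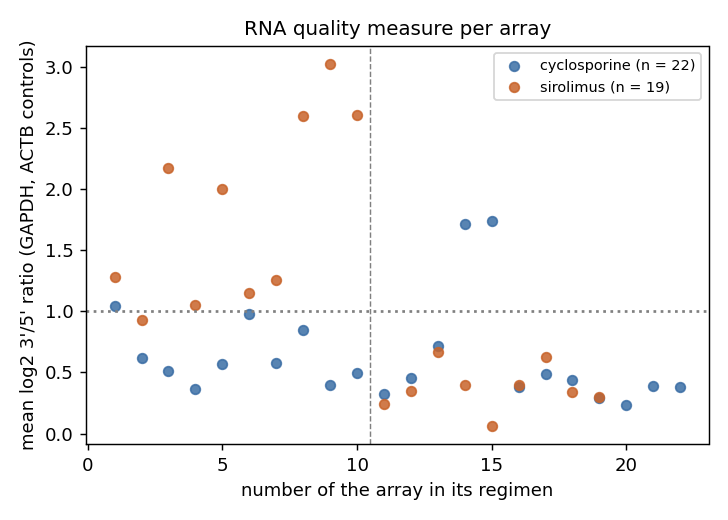
Mean log2 3' to 5' ratio of the GAPDH and ACTB controls in each array against its number in the regimen; the dotted line marks a log2 ratio of 1 and the dashed line parts the numbers 1 to 10 from the others. Above the dotted line lie 9 of 19 sirolimus and 3 of 22 cyclosporine arrays.

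**Figure D5:**
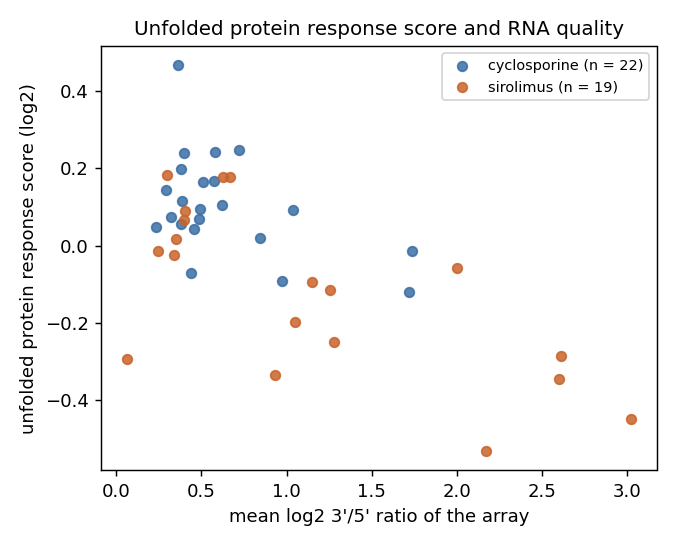
Unfolded protein response score (log2, relative to the mean of all arrays) against the mean log2 3' to 5' ratio, with 1 point per array. Of the sirolimus arrays, 16 of 19 lay below the cyclosporine median of the score.

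By limma with Benjamini-Hochberg adjustment, 4421 of 13372 tested probe sets passed an adjusted p of 0.05, 1931 higher and 2490 lower with sirolimus, with a median absolute log2 difference of 0.22 for the rises and 0.41 for the falls. The share of lower among these was 56.3%, against 41.9% with quantile normalization and 41.4% with arrays centred on their median. With the ratio as a covariate 812 passed (285 higher, 527 lower), 794 of them in common with the 4421. The median share of the log2 difference left in the 4421 was 0.694. A call could end because the difference shrank, because its SE grew or because the adjustment is stricter where fewer pass. Of the 94 called genes chosen by the rule for naming, 69 lost the call, 33 of them with a difference more than 1.5 times smaller and 36 within 1.5 times. In the 29 arrays with a ratio of at most 1 (10 sirolimus, 19 cyclosporine) 163 passed, and 1 without sirolimus replicate 15, where 3330 had an unadjusted p under 0.05. With no difference a share of 0.05 of the 13372 would be expected there, and 3330 is well above it, though genes are correlated. The single call thus does not show that the regimens are alike in these arrays. The ratio did not differ detectably between these 29 (0.43 ± 0.25 and 0.50 ± 0.19, p = 0.437), while the log2 number of probe sets above 500 was lower by 0.12 in the sirolimus arrays (p = 0.0113, not adjusted). Of these 10 sirolimus arrays 9 are those numbered 11 to 19, while the 19 cyclosporine arrays come from both sets of numbers. The 3330 therefore do not part regimen from number. With both regimens at numbers 11 or more, without sirolimus replicate 15 (8 and 12), limma gave 724 at an unadjusted p under 0.05. With the number above 10 as a covariate 4361 passed, but this covariate is nearly balanced between the regimens and could hardly change the calls. Without sirolimus replicate 15 alone 4729 passed. With each of the 41 arrays left out in turn, 25 of the 94 named genes lost the call at least once. All 25 lost it without sirolimus replicate 3, and each lost it without at least 1 other array as well, CLU in 26 of 41 omissions.

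Within the cyclosporine arrays the list scores were related to each other. The tubular injury score was higher where the extracellular matrix score was (r = 0.887, permutation p = 1e-05, the smallest the resamples can give; rho = 0.877, p = 1e-05; adjusted p = 8e-05 for both) and lower where the proximal tubule score was higher (r = -0.801, p = 2e-05, adjusted p = 8e-05; rho = -0.764, p = 0.00011, adjusted p = 0.00044). Without the 2 arrays farthest from the median injury score, r was 0.802 and -0.641. The T and NK cell score had r = 0.587 with extracellular matrix (p = 0.00425, adjusted p = 0.0113; rho = 0.42, p = 0.0541, adjusted p = 0.108; r = 0.563 without the 2 farthest) and r = -0.448 with the proximal tubule score (p = 0.0343, adjusted p = 0.0686; rho = -0.387, p = 0.0763, adjusted p = 0.122; r = -0.465 without the 2 farthest). In the sirolimus arrays injury and extracellular matrix had r = 0.399 (p = 0.0951, adjusted p = 0.127) and rho = 0.684 (p = 0.00167, adjusted p = 0.00445), with r = 0.926 without the 2 farthest and 0.964 without replicate 15. Injury and proximal tubule had r = 0.44 (p = 0.0834, adjusted p = 0.127) and rho = 0.195 (p = 0.422, adjusted p = 0.482), with r = 0.309 without the 2 farthest and -0.0454 without replicate 15. T and NK cells had r = 0.172 (p = 0.487, adjusted p = 0.557) and rho = 0.0509 (p = 0.839, adjusted p = 0.839) with extracellular matrix, and r = -0.0488 (p = 0.848, adjusted p = 0.848) and rho = -0.37 (p = 0.12, adjusted p = 0.16) with the proximal tubule. Without the 2 farthest these were -0.357 and -0.068, and without replicate 15 they were 0.411 and -0.628. The p-values were adjusted over the 8 relations computed. Within the cyclosporine arrays numbered 1 to 10 and 11 or more (n = 10 and 12), injury had r = 0.8 and 0.922 with extracellular matrix and -0.629 and -0.838 with the proximal tubule, and T and NK cells had 0.653 and 0.591 with extracellular matrix and -0.258 and -0.658 with the proximal tubule. Within the sirolimus arrays (n = 10 and 8) these were 0.883 and 0.96, 0.164 and -0.925, -0.135 and 0.771, and -0.919 and -0.561, in the same order.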

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

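Tests given the 3' to 5' ratio, in low-ratio or high-ratio arrays, without sirolimus replicate 15 or the 2 arrays with the most muscle, without _x_at probe sets, at a matched ratio and by array number were chosen after the data were seen. The 4421 called probe sets (1931 higher, 2490 lower) stayed within 1.5 times under both other scalings, other floors, the pseudocount, array weights, either filter, the variance settings and Wilcoxon's and Welch's tests (2965 to 5150), and between 3199 and 5377 when each array was left out in turn. The first residual component as a covariate gave 6302. It is unrelated to the regimen by construction, so it left each difference as it was and altered only the SE. It cannot show whether a hidden property lies behind the calls. Their split moved more: 2959 were higher with arrays centred on their median, 1274 with array weights, 1039 with the filter at the 60th percentile and 2919 with the first residual component as a covariate. By construction fewer passed with a fold of at least 1.5 (492, 15 higher and 477 lower), an adjusted p under 0.01 (1340, 408 and 932) or 1 probe set per gene (2630, 1177 and 1453). Given the ratio 812 passed (285 and 527), and 614 (237 and 377) without sirolimus replicate 15 as well. The low-ratio arrays gave 163 (39 and 124), and 1 (1 and 0) without that array. The high-ratio arrays, 9 against 3, gave 0 with limma and 934 at an unadjusted p under 0.05. The arrays numbered 1 to 10 gave 7188 (3410 and 3778), those numbered 11 or more 0 with limma, with or without replicate 15 (683 and 724 at an unadjusted p under 0.05), and the arrays with a ratio of 0.8 to 1.8, 5 against 5, gave 13 (1 and 12). The number above 10 as a covariate left 4361 (1908 and 2453), but it is nearly balanced between the regimens and could hardly change the count. The shared numbers do not pair the arrays: the correlation of same-numbered deviations ran from -0.38 to 0.401 over 19 numbers, and 1 sirolimus array correlated best with its own number; with the number as a replicate block 4066 passed (1742 higher, 2324 lower). The count of shifted lists, 1, became 2 with quantile normalization (calcineurin and NFAT genes joined), and between 1 and 2 when each array was left out: 2 without cyclosporine replicate 21 or without sirolimus replicate 17. It became 10 in the arrays numbered 1 to 10. It became 0 with array weights (unfolded protein response adjusted p = 0.0532), the replicate block (0.0703), both camera tests, the ratio as a covariate with or without replicate 15, the low-ratio and high-ratio arrays, and the arrays numbered 11 or more with or without replicate 15 (the lists at an unadjusted p under 0.05 were 2 with array weights, 8 with the block, 8 and 0 with camera at a preset and an estimated correlation, 3 and 2 with the ratio, 2 in the low-ratio arrays, 0 there without replicate 15, 7 in the high-ratio arrays and 0 and 0 in those numbered 11 or more, against 8 in the main test); the cause was not tested. The unfolded protein response difference ran from -0.27 to -0.08 over settings other than the split by number, which gave -0.42 in the lower numbers and -0.0229, or 0.0190 without replicate 15, in the higher. With quantile normalization 7 lists that did not pass changed sign: endothelial, smooth muscle, vasoactive, sterol, glycolysis, oxidative phosphorylation and immediate early. Others shrank, podocyte from -0.13 to -0.04, mTOR from -0.07 to -0.01 and metallothionein from -0.22 to -0.12. Of the relations in sirolimus arrays, without replicate 15, T and NK cells with proximal tubule moved to -0.628, injury with extracellular matrix to 0.964 and injury with proximal tubule from 0.44 to -0.0454. In sirolimus arrays numbered 1 to 10, T and NK cells with proximal tubule had -0.919 and injury with extracellular matrix 0.883, and in those numbered 11 or more without replicate 15 these had -0.561 and 0.96, T and NK cells with extracellular matrix 0.771 and injury with proximal tubule -0.925. The RNA quality difference stayed at 0.496 without a floor, which touched no control value, and was 1.168 in the arrays numbered 1 to 10 and -0.2524 in the others. Of 94 called genes named, 69 lost the call given the ratio (36 with a difference within 1.5 times of the main one, 5 of these no smaller, and a median share left of 0.678). With quantile normalization 20 lost it and with array weights 31, and no called gene changed sign in any of these. In the low-ratio arrays 90 lost it. Those that lost it with the same sign were 87 in the high-ratio arrays and 92 in the low-ratio arrays without replicate 15. Signs turned for COL1A1 (-0.0339), CLDN16 (0.0625), TJP1 (0.0762), SMTN (-0.103), EIF4E (0.108), FKBP1A (0.0628) and PCNA (0.0139) in the high-ratio arrays, and for B2M (0.0700) and CLU (0.0347) in the low-ratio arrays without replicate 15. In the arrays numbered 11 or more without it, signs turned for GLUD1 (0.0268), SNX2 (0.0699), CCN2 (0.143), CD5 (-0.0243), MRC1 (0.119), B2M (0.185), CIITA (-0.00266), CD59 (0.0394), CLU (0.0916), LRP2 (0.0280), CUBN (0.277), KCNJ1 (0.175), TJP1 (0.0571), PODXL (0.192), EMCN (0.147), EDNRB (0.0598), RCAN1 (0.0445), TFEB (-0.0624), FKBP1A (0.0537), MSMO1 (0.0524), SLC2A3 (-0.00633), HSPA5 (0.236), PCNA (0.0312), PLK1 (-0.0945), MKI67 (-0.0265) and SOD1 (0.00901), and the other 68 called genes named lost the call. Dim signals limit what the table can show, since values under the floor, 20% of the table by its definition, were set to it. Floors at the 5th and 40th percentile gave 4414 and 4264 called probe sets.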

Other observations

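Tests on the skeletal muscle genes, on the Alu control, on the rank of the ratio of sirolimus replicate 15, on the count without that array, on the count given the ratio and on the count given the number were chosen after the values were seen. The tissue make-up of the arrays varied beyond the regimen. In sirolimus replicate 15 the myosin gene MYH2 had an intensity of 8404 and the creatine kinase gene CKM 6974, against medians of 22.1 and 25.5 in the other arrays, while the kidney transporter genes SLC3A1 and SLC22A8 had 40.2 and 57 against medians of 2379 and 1477. Cyclosporine replicate 20 had 2532 for MYH2 and 3103 for CKM. Fat markers stood out less in sirolimus replicate 15: FABP4 had 372.4 against a highest other value of 135.6, and 1 of 6 adipose genes lay 4-fold or more above the median.

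The 4421 probe sets called between regimens are the first pattern, and their number may come in part from RNA quality. Across tested probe sets, the log2 difference between regimens had r = 0.641 with the slope on the 3' to 5' ratio within the cyclosporine arrays alone, in which the regimen does not vary, and r = 0.336 without the 2 cyclosporine arrays farthest from the median ratio; 92.2% of the called and 79.7% of all tested probe sets had the sign of that slope, and genes are not independent replicates. As the whole cause, a linear trend with this measured ratio is argued against by the 794 called probe sets still called given the ratio. RNA quality itself as the whole cause is not tested by this. The ratio rests on GAPDH and ACTB alone, and calls can stay where it follows RNA quality imperfectly. Muscle in sirolimus replicate 15 is argued against by the 4729 called without it. This omission does not test muscle or fat signal in other arrays, such as sirolimus replicates 2 and 7 (adipose and skeletal muscle score 1.38 and 1.20). Among arrays numbered 1 to 10 that score differed by 0.48 ± 0.32 between regimens (SE, permutation test, adjusted p = 0.199). Given the number, 4243 were still called. This says little about a shift between lower and higher numbers shared by both regimens. Numbers 1 to 10 hold 10 of 19 sirolimus and 10 of 22 cyclosporine arrays, and with this near balance the covariate could hardly end calls. Chance is argued against for the 4421: 1 of 100 splits of the arrays, the real one and the fewest possible, gave as many, and the highest other gave 1. The same holds for the 812 given the ratio (1 of 100, highest other 12). It does not hold for the 1 in the low-ratio arrays without replicate 15 (5 of 100, highest other 1301, a split that points to a structure of these arrays). Whether that drop to 1 came from fewer arrays cannot be told apart: 9 of 100 random draws of 9 sirolimus and 19 cyclosporine arrays called as few (median 1880), but the draws with fewer calls also had a smaller difference in the ratio (r = 0.704). By the bound set beforehand the draws would have favoured fewer arrays, and the verdict was changed after the result was seen.

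Within this pattern, most calls rest on the arrays numbered 1 to 10, where limma called 7188, against 0 in those numbered 11 or more (683 at an unadjusted p under 0.05). Of the 94 called genes named, BLK, CFB, HK2, IER3, NPR1 and PLIN1 did not pass in the arrays numbered 1 to 10. Chance is argued against for the 7188 (1 of 100 splits, highest other 1) and for the 3790 probe sets whose difference depends on the number (1 of 100, highest other 1). The cut at number 10 was chosen after the data were seen, and neither test repeated that choice. Fewer arrays are argued against as the cause by the 3790, which show that the differences themselves were not the same. By the bound set beforehand, 39 of 100 draws of 8 sirolimus and 12 cyclosporine arrays, which also called 0, would have favoured it. Those draws mix both sets of numbers, and the verdict was changed after the result was seen. RNA quality is a candidate explanation, and whether it is the whole of it cannot be told apart. Of probe sets called in the arrays numbered 1 to 10 outside a ratio of 0.8 to 1.8, a median share of 0.0886 of the difference was seen between 5 sirolimus and 5 cyclosporine arrays within that range. This is under the 0.2 set beforehand in favour of RNA quality, and 63.8% of these probe sets had the same sign. The matched arrays cross the split by number: the 5 sirolimus arrays are all numbered 1 to 10, but cyclosporine replicates 14 and 15 (ratios of 1.72 and 1.74) are among the 5 cyclosporine arrays. However, 398 of the 7188 were still called in the same direction given the ratio, and this too was put to undecided after the result was seen. The matched sirolimus arrays are also the ones with the lowest ratios of their numbers, and 1 of the 10 lay within the range of the cyclosporine arrays numbered 1 to 10, so another property of sirolimus arrays 1 to 10 that goes with the ratio (the biopsies, their handling or the array run) stays open. Between lower and higher numbers limma called 3577 probe sets within the sirolimus arrays without replicate 15, and 247 within the cyclosporine arrays. Sirolimus arrays 1 to 10 thus differed from other arrays of their own regimen. In the arrays numbered 11 or more the ratio did not differ detectably (permutation p = 0.23), and the regimens gave 0 calls. An effect of the regimen too small for these arrays to show stays open, as does one that only some of the biopsies would show.

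The second pattern is the _x_at probe sets, 14 of the 15 largest rises and 275 of all 1931, or 14.2% against 13.9% of those tested. More Alu repeat sequence in the labelled RNA of the sirolimus arrays is argued against by the Alu control, which was -0.0822 ± 0.0689 (SE) on the log2 scale in sirolimus minus cyclosporine. RNA quality stays open: the median slope on the ratio within cyclosporine arrays of the called _x_at probe sets that rose was 0.158 log2 per unit, between the 0.05 below which it would have counted against it and the 0.2 above which it would have counted for it, and for the 14 among the largest rises alone it was 0.251. No biological explanation was tested.

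The third pattern is that sirolimus replicate 15 stood apart, with a median correlation with the other arrays of 0.76 across the tested probe sets (log2, floored) against at least 0.856 for each other array, and of 0.86 against at least 0.922 across all probe sets but controls and those of XIST, TSIX and Y-linked genes, without a floor. Poor RNA as measured by the 3' to 5' ratio is argued against, since its log2 ratio of 0.06 was the lowest (rank 41 of 41). The ratio rests on GAPDH and ACTB alone, and whether muscle tissue alters it was not tested. Skeletal muscle tissue in the biopsy is a candidate explanation, since 8 of 8 muscle genes of the list lay 4-fold or more above the median of the others. A first, stricter rule, 4-fold above the highest other array, was met by 1 of the 8 and was replaced after that result, because cyclosporine replicate 20 carried muscle signal too. Whether it held kidney tissue at all cannot be told apart here: 16 of 22 proximal tubule markers lay 4-fold or more below the median, and of the 6 within 4-fold SLC5A2 had an intensity of 152 against a median of 303 and a lowest other value of 116, and SLC22A7 107 against a median of 195. Its loop of Henle score was -2.47 and its distal tubule and collecting duct score -1.87, against at least -1.19 and -0.48 in the other arrays. The podocyte score, -0.23, lay within the range of the others (lowest -0.51).

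A further hypothesis was that tubular injury and proximal tubule markers are related differently under the regimens, with r = -0.801 in the 22 cyclosporine arrays and -0.0454 in the 18 sirolimus arrays without replicate 15. Permuting the regimen of group-centred scores gave p = 0.04 for this difference of 0.755, and adjusted p = 0.16 over the 4 relations, so the difference did not pass. Within the sirolimus arrays r was 0.164 in the numbers 1 to 10 and -0.925 in the 8 others. Within the cyclosporine arrays r was -0.629 and -0.838 in these numbers. The weaker relation under sirolimus was thus seen in the numbers 1 to 10 alone, where RNA quality differed too. A p of this size does not show that the relations are alike, so the bound set beforehand, an adjusted p of 0.05 or more, was too weak to count against the hypothesis; that bound was met, and the verdict was changed to undecided after the result was seen.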
